A study of Homo sapiens with 2 samples.

How the data were processed

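RNA sequencing measured gene expression in 2 libraries of U87MG, an established human glioblastoma line, grown as glioma spheres for a week in stem cell medium. Per the labels' protocols, the cells carried a lentiviral control shRNA or an shRNA against TRIP13 and were selected with puromycin. Libraries were made from total RNA with the NEBNext Ultra kit. Each group held 1 library, named control shRNA or TRIP13 shRNA after its label. TRIP13 itself was higher in the library with the TRIP13 shRNA label, so which shRNA that library carried is not certain and it is called the library labelled TRIP13 shRNA throughout.

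The authors deposited FPKM values, which relate the fragments of a gene to the length of its merged exons and to a library total, for 58735 genes. HISAT2 2.0.5, featureCounts 1.5.0-p3, edgeR and build hg38 are named per the submitters' processing notes, which give neither the role of each tool nor its settings. The annotation and the strand setting are not given in the sources used here. The identifiers, positions and strands of 58735 genes equalled those of GENCODE release 29. Overlapping and antisense genes could therefore share reads, and members of near-identical families could have their reads split by the authors' counting.

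The deposited FPKM values multiplied by gene length were whole multiples of 1 step, 51.5981, in both libraries. Within a tolerance of 0.001 of a read, 100% of the values were whole. The recovered totals were 19903836 reads for the library labelled TRIP13 shRNA and 18871063 for the control library, a depth ratio of 1.055. The common step corresponds to a total of 19380571, which is the geometric mean of both totals. The deposited values were thus divided by a common total, and the ratio of FPKM equals the ratio of reads with no correction for depth (log2 depth ratio 0.08). Own totals were used as an alternative chosen after seeing the data. A count of 3 reads in a gene of 1 kb corresponds to 0.155 FPKM in either library.

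Genes were compared as log2((FPKM + 1) in the library labelled TRIP13 shRNA / (FPKM + 1) in the control library), called the log2 ratio, which understates differences of weakly expressed genes. Protein-coding genes with a mean FPKM of 1 or more were used, 10671 of 19951. With 1 library per group there is no replicate error, no test and no p-value, and every difference describes these libraries rather than the conditions. A fixed size rule counted genes with a log2 ratio of 1 or more, or of -1 or less. Ratios of FPKM are given with 95% exact (Clopper-Pearson) intervals from the split of the recovered reads. These intervals, and the floor of 3 reads used where a library had none, cover counting error only, since reads without molecular identifiers are not independent molecules.

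Before the data were examined, 31 gene lists were fixed, together with the size rule, the alternatives except the 1 named above, and the rule for named genes. That rule took TRIP13, MYC and FBXW7, the 12 highest and 12 lowest log2 ratios outside chromosome Y, and up to 2 members at each end of each list. For lists with at least 5 members, the median log2 ratio was set against 10000 random lists of the same size matched in 20 bins of mean expression. Its percentile among them is a description of these libraries. A list is said to lie outside the random range when its percentile is below 2.5 or above 97.5. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of 5 or more, rescaling to TPM, a median ratio of 1, scaling without mitochondrial and the 50 most abundant genes, recovered reads with 5 added at equal totals, genes of every biotype, and random lists matched in 5 bins or also on gene length. The spread of a list median was taken from 2000 bootstraps of its members.

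The calculations were tested on simulated data for this comparison with 10660 genes past the filter. Reads were recovered exactly for 100% of the genes, and the counting interval held the true ratio for 95.2% of unchanged genes. That true ratio was the depth ratio of 1.055, not 1, so comparisons of an interval with 1 below still carry the difference in depth. The size rule recovered 50 of 50 genes made 4-fold higher and 49 of 50 made 4-fold lower. It recovered 44 of 50 made 2.5-fold higher, 29 of 50 made 2.5-fold lower and 0 of 10460 unchanged genes. Of 200 random lists without a shift, 2.5% lay outside the random range. The simulated libraries differed by counting error and the set changes only, with no variation between cultures or library preparations. These rates are therefore not error rates for the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.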

Results

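Gene expression was measured in U87MG glioma spheres carrying a control shRNA or an shRNA against TRIP13, an AAA+ ATPase that remodels the spindle checkpoint protein MAD2. Each group held 1 library, so no difference below has a replicate check. The library labelled TRIP13 shRNA held 19903836 recovered reads and the control library 18871063. At least 1 read was found for 25143 and 27172 genes respectively. Thinning the deeper library to the depth of the other left a median of 24971 genes over 20 draws. Mitochondrially encoded genes took 4.40% of the reads in the library labelled TRIP13 shRNA, 1.10 times their share in the control library, and lincRNAs took 0.534% and 0.818%.

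The comparison asks how gene expression differs when TRIP13 is targeted in glioma spheres. TRIP13 (ENSG00000071539, hg38 chromosome 5, 892643 to 919357, plus strand) was higher in the library labelled with its shRNA, against the label. Its FPKM was 23.1 in the library labelled TRIP13 shRNA and 11.9 in the control library, from 1593 and 819 reads. The FPKM ratio was 1.95 (95% counting interval 1.79 to 2.12) and the log2 ratio 0.90. Of the exon length of TRIP13, 5.11% is shared with other annotated genes. Every direction given below is therefore a direction between libraries as labelled. MYC, a transcription factor that drives growth, stood at 44.6 against 39.9 FPKM, a ratio of 1.12 (1.06 to 1.18). FBXW7, the ubiquitin ligase subunit that marks MYC for degradation, stood at 2.22 against 2.09 FPKM, a ratio of 1.06 (0.932 to 1.21), which was not distinguishable at this depth. No direction is read for MYC either, since its log2 ratio of 0.16 turned to -0.03 with the median ratio set to 1.

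The 12 lowest log2 ratios included 4 members of the NF-kB and cytokine list (IL1B, PTGS2, CXCL8 and IL6) and MSMO1 of the cholesterol list, and ID1, ID2 and ID3 were among the 12 highest. IL1B, an inflammatory cytokine, was 141-fold lower in the library labelled TRIP13 shRNA (121 to 165), at 2.8 against 394 FPKM. The cytokines IL33 (0.254 against 17.4 FPKM), CXCL8 (22.4 against 295) and IL6 (1.52 against 27.8) were also lower. So were PTGS2, the inducible cyclooxygenase (3.41 against 59.9), and IL1RN, the interleukin 1 receptor antagonist (2.46 against 39). For IL6, 20.7% of the exon length is shared with other annotated genes. SCD, the stearoyl-CoA desaturase, was 23.5-fold lower (22.7 to 24.4), at 32.1 against 756 FPKM, and MSMO1, a sterol synthesis enzyme, was 10.7-fold lower (9.89 to 11.6). CHI3L1, a secreted glycoprotein, had 57.8 against 670 FPKM, TCIM 1.31 against 28.3 and the keratin KRT79 5.38 against 63. SAA1, an acute phase protein with a close paralog in SAA2, had 0 reads against 144, at least 48-fold lower against the floor of 3 reads.

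ID3, ID1 and ID2, inhibitors of basic helix-loop-helix transcription factors, were 20.1-fold (16.6 to 24.6), 11.4-fold (10.1 to 12.8) and 9.53-fold (7.54 to 12.2) higher in the library labelled TRIP13 shRNA. ID3 stood at 64.1 against 3.19 FPKM and ID1 at 146 against 12.8. STC2, a secreted glycoprotein, had 106 against 10.2 FPKM, and TGFBI, an extracellular matrix protein induced by TGF-beta, had 545 against 119. The homeobox gene DLX2 had 7.11 against 0.764 FPKM, KBTBD11 7.87 against 0.6 and the small GTPase RHOB 27.5 against 4.85. CPA4, FAM111B and AMIGO2 had log2 ratios of 2.05, 1.99 and 1.84. CGB8, a chorionic gonadotropin beta gene, had 235 against 4 reads, a ratio of 58.8 (22.6 to 217). It belongs to a cluster of near-identical genes whose reads could be split in counting, with CGB5 at 22 against 4 and CGB7 at 87 against 23 reads, and its value is uncertain.

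**Figure D1:**
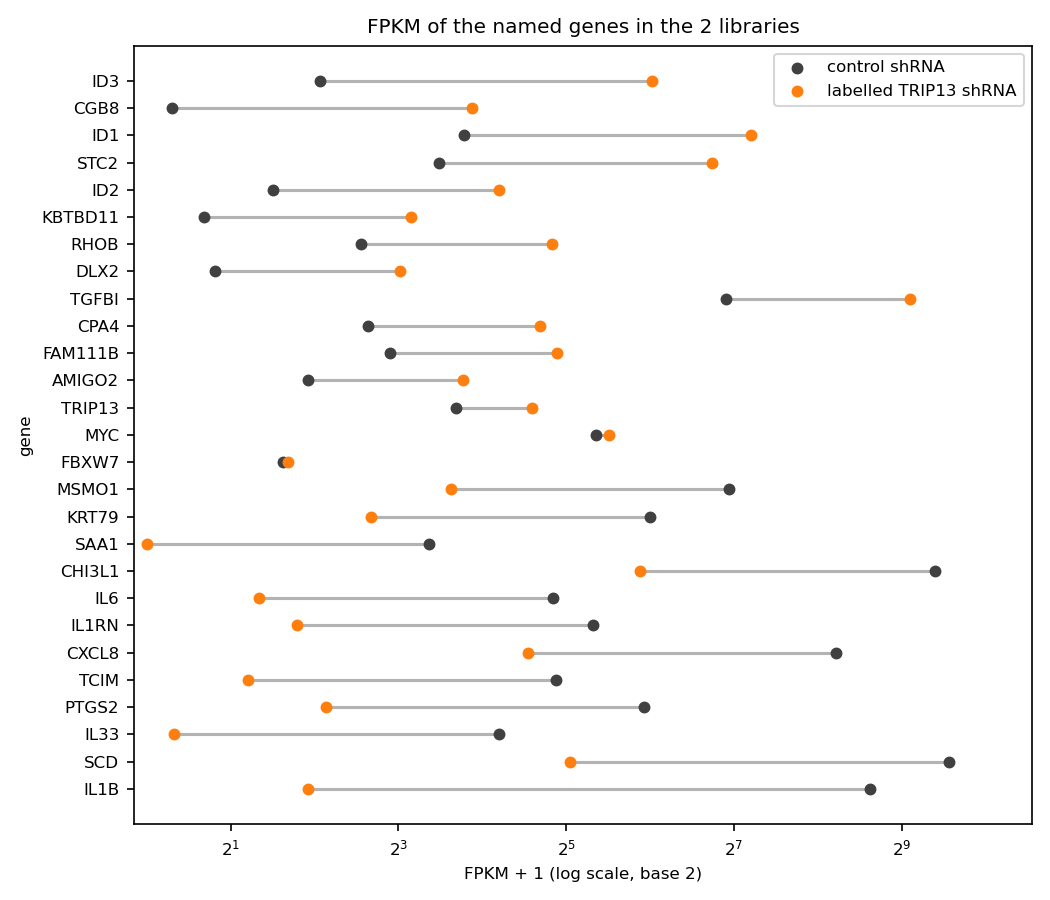
FPKM + 1 on a log axis for 27 genes (TRIP13, MYC, FBXW7 and the 12 highest and 12 lowest log2 ratios), 1 line per gene, with a grey point for the control library and an orange point for the library labelled TRIP13 shRNA (1 library each, no error bars). The points of IL1B lie farthest apart, at 2.8 against 394 FPKM, and TRIP13 lies higher in the library labelled TRIP13 shRNA, at 23.1 against 11.9 FPKM.

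Among 10671 protein-coding genes, 232 were at least 2-fold higher and 447 at least 2-fold lower in the library labelled TRIP13 shRNA, so 34.2% of the genes past the size rule were higher. These counts are not corrected for depth. Dividing each library by its own total, chosen after seeing the data, gave 178 higher and 513 lower (25.8% higher, of 10673 genes). With the median ratio set to 1 it was 113 higher and 617 lower (15.5% higher), and after rescaling to TPM it was 277 higher and 956 lower (22.5% higher, of 12183 genes). TPM values are larger than the FPKM values of either library, so that alternative also lowers the weight of the pseudocount and lets more genes past the filter. The median log2 ratio of all tested genes was 0.12, and the median ratio of 1 and TPM shifted it by -0.17 and -0.12. List medians are therefore read against matched random lists, which carry the same shift.

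Genes of DNA replication, mitosis and MYC targets were higher together in the library labelled TRIP13 shRNA, which goes with the higher TRIP13 level there. All 26 replication and G1/S genes lay above 0 and 16 were at least 2-fold higher, with a median log2 ratio of 1.08, above all 10000 random lists. MYBL2, a transcription factor of the cell cycle, had 93.6 against 26 FPKM and RRM2, a ribonucleotide reductase subunit, 46.5 against 13.3, while CHEK1 had the lowest log2 ratio of the list, 0.33. All 28 spindle checkpoint and mitosis genes lay above 0 with 4 at least 2-fold higher, a median of 0.63, again above all random lists. ZWINT, a kinetochore protein, had 4492 against 1818 reads and cyclin A2 (CCNA2) 69.4 against 28.5 FPKM, and the kinase TTK had 5.52 against 4.86 FPKM, with a log2 ratio of 0.16 that turned to -0.01 with the median ratio set to 1. Of 29 MYC targets, all lay above 0 and 6 were at least 2-fold higher, with a median of 0.73, above all random lists. The nucleolar proteins NOP56 (24.7 against 9.74 FPKM) and BOP1 (31.6 against 13.4) were at the top. Of 10 replication-dependent histone genes with values, 6 passed the FPKM filter, so the list does not cover the others, HIST1H4C and HIST1H3A among them. The median of the 6 was -0.40 at percentile 2.7, inside the random range, and at 2.2 when random lists were matched in 5 bins. Whether the other histone genes moved with the replication genes cannot be read from these 6. HIST1H1C, at 9.81 against 27.6 FPKM, was the 1 member at least 2-fold lower, and the counting intervals of HIST2H2AC (0.446 to 1.27), HIST1H2BD (0.488 to 1.21) and HIST1H2AC (0.624 to 1.09) included 1.

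Inflammatory genes were lower in the library labelled TRIP13 shRNA. Of 20 NF-kB and cytokine genes, 17 were at least 2-fold lower and 0 at least 2-fold higher. The list median was -1.83, below all random lists, and it ranged from -2.38 to -1.08 over the alternatives. BIRC3, an inhibitor of apoptosis, had the highest log2 ratio of the list, 0.03, at 1.53 against 1.48 FPKM, and no direction is read for it, since its ratio of 1.03 (0.852 to 1.25) was not distinguishable from 1 and its log2 ratio turned to -0.09 with the median ratio set to 1. Interferon response genes had a median of -0.12 over 13 members, with 998 of 10000 random lists below it, and this median was above 0 among genes with a mean FPKM of 5 or more. In that list OASL had 2.6 against 5.59 FPKM and OAS3 6.15 against 3.11. Microglia and macrophage markers were low in both libraries. Of them, 2 passed the FPKM filter, TMEM119 at 0.696 against 4.4 FPKM and CSF1R at 3.31 against 3.75.

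Sterol synthesis genes were lower as a group, with 19 of 21 at least 2-fold lower, a median of -1.81 and no random list below it. HMGCS1, the HMG-CoA synthase, had 5.57 against 62.8 FPKM and EBP, a sterol isomerase, 30.3 against 56. PMVK, the phosphomevalonate kinase, was the exception at 47.9 against 20.4 FPKM, a log2 ratio of 1.19.

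MAPK feedback and immediate early genes had a median of -0.88 (range over the alternatives -1.07 to -0.58), below all random lists, with 6 of 20 at least 2-fold lower. The phosphatase DUSP6 had 5.28 against 40.7 FPKM and FOS 1.77 against 11.5, while FOSL1, a FOS family member, was higher at 479 against 259. The TGF-beta and BMP list had a median of 0.55 at percentile 99.9 (range 0.33 to 0.65), with a bootstrap interval over its members of -0.26 to 1.86 that includes 0. Of its 14 members 9 lay above 0 and 5 below, and 5 were at least 2-fold higher, among them ID1 and ID3. CTGF, a matricellular protein, went the other way at 4.17 against 12.2 FPKM. The PI3K and FOXO list had a median of -0.26 at percentile 0.4 (range -0.43 to -0.14) with 2 of 16 at least 2-fold lower, the receptor PDGFRB (1.74 against 12.4 FPKM) and CCNG2 (1.81 against 6.24).

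Collagens and matrix genes had a median of -0.41 over 17 members, 5 at least 2-fold lower, and 3 of 10000 random lists lay below it (range -0.61 to -0.22). FBLN1 had 0.0779 against 3.63 FPKM and the laminin LAMA4 3.44 against 13.3, while COL5A1 had 13.3 against 12.3, a log2 ratio of 0.10 that turned to -0.08 with the median ratio set to 1. The epithelial-mesenchymal transition and invasion list had the same median, -0.41, below all random lists, with a bootstrap interval of -0.80 to 0.20 that includes 0. Of its 21 members 12 lay below 0 and 9 above, with 5 at least 2-fold lower and 1 at least 2-fold higher. The median ranged from -0.65 to -0.05, the latter among genes with a mean FPKM of 5 or more. Fibronectin (FN1) had 85.3 against 329 FPKM, and LOX, a collagen cross-linking enzyme, 44.9 against 24.4. Of 14 fibroblast and pericyte markers, 8 passed the filter. All 8 lay below 0, with a median of -0.42 at percentile 0.5 and 2 at least 2-fold lower, PDGFRB and LUM (2.08 against 7.55 FPKM). This list shares 3 members with the matrix list, and PDGFRB with the PI3K and FOXO list. Hypoxia and glycolysis genes had a median of -0.14 at percentile 0.2 (range -0.32 to -0.10), with a bootstrap interval of -0.40 to 0.14 that includes 0. ALDOC and SLC2A3 had 6.38 against 22.5 and 12.9 against 36.6 FPKM, while ENO2 had 100 against 61.8.

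Of the 26 lists with a median, 12 lay outside the random range and 14 inside it, the histone and interferon lists among the latter. DNA end joining genes had a median of 0.15 at percentile 53.5, with XRCC5 at 77.3 against 52.7 FPKM and XRCC6 at 97 against 112. FBXW7 and its substrates had a median of 0.11 at percentile 28.6, which turned to -0.06 with the median ratio set to 1. In that list CCNE1, cyclin E1, had 12.5 against 3.78 FPKM, KLF2 8.77 against 2.25, SREBF1, a regulator of lipid synthesis and the 1 member at least 2-fold lower, 11.3 against 23.6 and MCL1 80.6 against 157. Of the 23 genes of the glioma stem cell list, 10 passed the filter, and SOX2 and PROM1 were among those that did not. The 10 tested genes had a median of -0.01 at percentile 22.3. This median turned to 0.85 among genes with a mean FPKM of 5 or more and was -0.48 under TPM. In that list SOX9 had 0.747 against 4.39 FPKM and OLIG2 0.339 against 2.72, opposite to ID1 and ID3 of the same list. The p53 targets had a median of 0.25 at percentile 78.9, with AEN at 21.2 against 9.11 FPKM and GDF15 at 23.6 against 68.9. The unfolded protein and amino acid stress list had a median of 0.13 at percentile 31.6, below 0 under TPM and under the median scaling, with PSAT1 at 52.8 against 19.2 FPKM and DDIT4 at 15.2 against 62.4. WNT targets, of which 7 of 15 were tested, had a median of 0.33 at percentile 93.6, with DKK1 at 5.8 against 1.47 FPKM. NOTCH targets, of which 5 of 14 were tested, had a median of -0.30 at percentile 13.1, with the receptor NOTCH3 at 0.538 against 9.28 FPKM. YAP and TEAD targets had a median of -0.11 at percentile 4.9, above 0 among genes with a mean FPKM of 5 or more, with NT5E at 79.3 against 230 FPKM and CRIM1 at 24 against 11.4.

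Ribosomal protein genes had a median of 0.28 at percentile 47.0, mitochondrially encoded mRNAs 0.27 at 42.0, nuclear genes of oxidative phosphorylation 0.41 at 95.3 and housekeeping genes 0.41 at 91.4. These medians stayed above 0 under each scaling tried, and 0 members of these lists were at least 2-fold higher or lower. Markers of other brain cell types were too few for a median. Neuronal markers went both ways, with SNAP25 at 5.93 against 6.26 FPKM, MAP2 at 1.33 against 1.75, SYT1 at 0.858 against 1.93 and GAD1 at 1.64 against 1.03. All 4 astrocyte markers tested lay below 0, GJA1 at 62.3 against 103 FPKM, GLUL at 11.7 against 25, ALDOC at 6.38 against 22.5 and SLC1A3 at 7.91 against 10.6. Of the oligodendrocyte lineage markers, CSPG4 and CNP had 18.5 against 13 and 17.1 against 10.1 FPKM, while OLIG2 was at least 2-fold lower at 0.339 against 2.72. KDR, the 1 endothelial marker past the filter, had 2.85 against 4.52 FPKM. Below the filter, VWF had 6 against 75 reads and PECAM1 1 against 45, while ERG had 14 against 11.

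**Figure D2:**
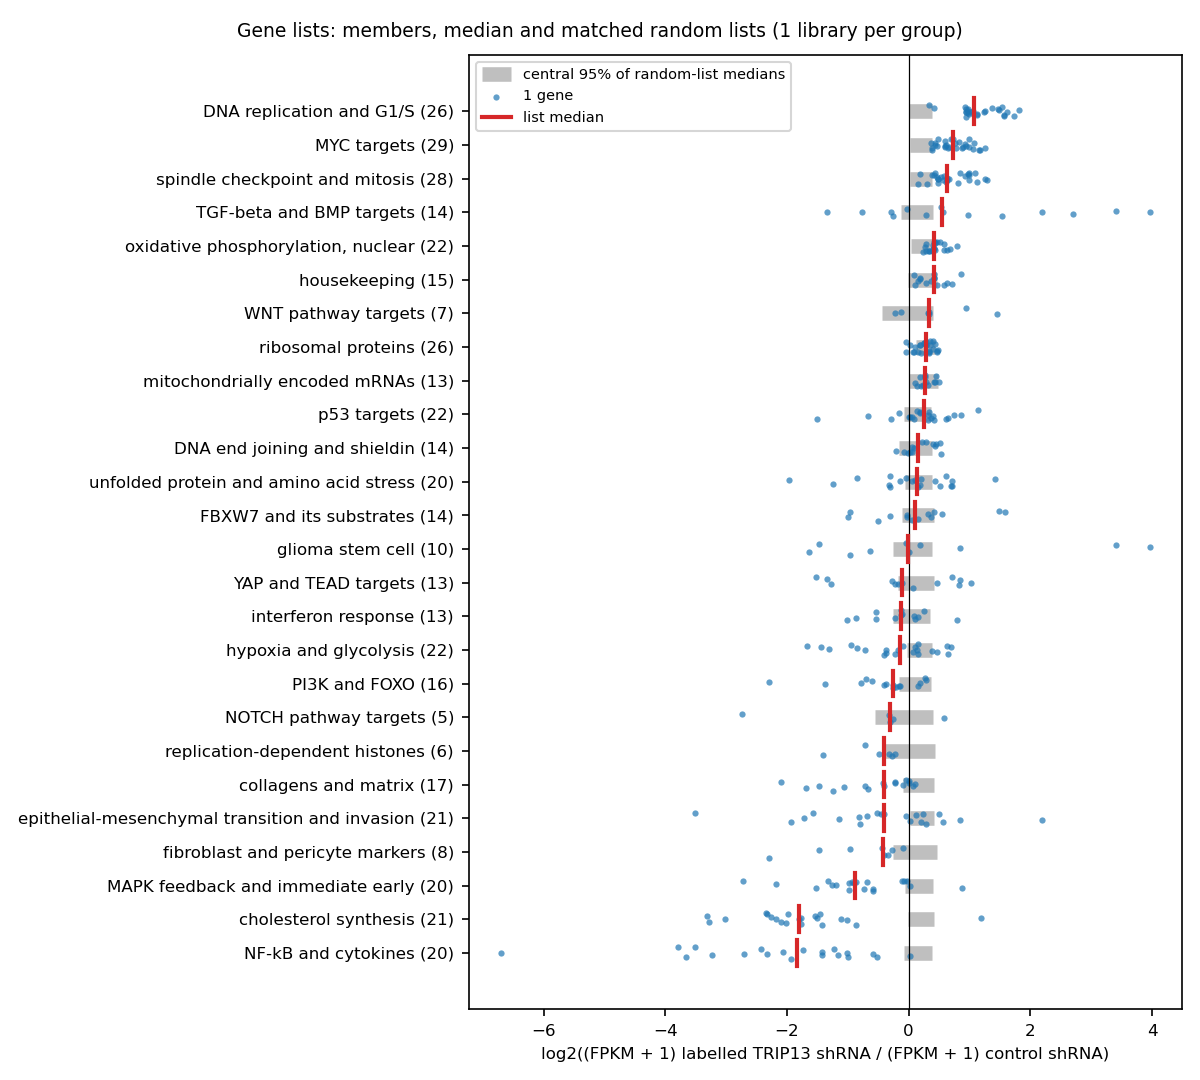
Log2 ratio of FPKM + 1 (library labelled TRIP13 shRNA over control library, 1 library each) for the members of 26 gene lists, with the number of members in brackets. Blue points are genes, red bars list medians and grey bars the central 95% of the medians of 10000 matched random lists. The replication median of 1.08 lies to the right of its grey bar and the cytokine and cholesterol medians of -1.83 and -1.81 lie to the left of theirs.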

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

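The tests of counting error, scaling, exchanged labels and movement with the cell cycle genes in this part were chosen only after the result was seen. Noncoding genes lie outside the comparisons above and showed differences beyond counting error. Of 2457 noncoding genes with a mean FPKM of 1 or more, 62 were at least 2-fold higher in the library labelled TRIP13 shRNA with a counting interval above 1, and 232 were at least 2-fold lower. As a class, lincRNAs took 0.534% of its reads against 0.818% in the control library, and antisense genes 0.360% against 0.463%. Processed pseudogenes took 0.343% in both. Among those with at least 50 reads, the highest log2 ratios were 2.87 for GGT4P, 2.78 for AL122125.1 and 2.71 for BISPR. The lowest were -4.25 for AC107016.1, -3.47 for LINC02392 and -3.38 for LINC02376. GGT4P, a pseudogene whose reads could be shared with its parent family, had 924 against 98 reads and BISPR had 347 against 3. These genes are reported as values with no explanation.

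TRIP13 was higher in the library labelled TRIP13 shRNA. Counting error and the scaling are argued against as causes, since the lower end of the counting interval of the ratio was 1.79 and the lowest log2 ratio over the scalings was 0.72. TRIP13 lay close to the cell cycle genes, here the mitosis and replication lists pooled. It lay -0.06 from their median log2 ratio of 0.97, so it may have moved with them. Exchanged labels cannot be told apart from correct ones, because TRIP13 lay at percentile 38.9 of 54 cell cycle genes, neither above nor below their range, and no other value here identifies the shRNA. An shRNA without lasting effect on the transcript, and differences between separately selected cells, also stay open and were not tested.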

How the results depend on the processing

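Dividing each library by its own total was chosen after seeing the data, and the other alternatives before. No paired analysis was possible because each group holds 1 library. The log2 ratio of TRIP13 stayed between 0.72 and 0.95. Of 132 named genes, 61 had an at least 2-fold difference, and 0 of these turned direction. No alternative could have turned them, since pseudocounts and filters keep the sign and the scalings shift log2 ratios by far less than 1. Smaller differences did turn with the median ratio set to 1, those of MYC, TTK, BIRC3 and COL5A1 among them. Over all named genes, 404 alternative values lay outside the counting interval and 752 inside. Of 231 alternative list medians, 209 stayed inside the bootstrap spread of the members. A mean FPKM of 5 or more gave no median for 3 lists with too few members left, those of WNT targets, NOTCH targets and histones. Percentiles under other matching kept their side in 51 of the comparisons, and the histone list passed to 2.2. Depth limits genes near 3 reads, where ratios rest on few reads in both libraries. Except where the construction of an alternative shows it, the cause was not tested.

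A pseudocount of 0.1 gave 408 genes higher and 677 lower with a median log2 ratio of 0.14, since weak genes are then shrunk less. A pseudocount of 5 gave 64 and 180 with a median of 0.07, TRIP13 at 0.74, replication genes at 0.92, MYC targets at 0.57, cytokines at -1.08, MAPK genes at -0.58, oxidative phosphorylation at 0.39 and histones at -0.23. Without a filter the median of all genes was 0.00, and with a mean FPKM of 5 or more it was 0.19 with 280 genes lower, of fewer genes tested. Rescaling to TPM gave 956 genes lower and turned the median to -0.01, while also lowering the weight of the pseudocount and the filter, with ribosomal proteins at 0.17, mitochondrial mRNAs at 0.16 and oxidative phosphorylation at 0.30. Setting the median ratio to 1 left 113 genes higher and turned the median to -0.05, with TRIP13 at 0.72, mitosis at 0.43, end joining at 0.01, replication at 0.89, MYC targets at 0.55, ribosomal proteins at 0.09, mitochondrial mRNAs at 0.07 and oxidative phosphorylation at 0.22. Scaling without mitochondrial and the 50 most abundant genes gave a median of 0.06, mitochondrial mRNAs at 0.20 and oxidative phosphorylation at 0.35. Recovered reads at equal totals gave 773 genes lower, a median of 0.06, and the latter lists at 0.20 and 0.34. Own totals gave 178 genes higher and 513 lower, a median of 0.05 and the same lists at 0.20 and 0.34. Genes of every biotype gave 737 lower and a median of 0.09, over more genes.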

Other observations

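The tests of scaling and of myeloid cells, and the check of the LXR list without NR1H3, in this part were chosen only after the result was seen, and those of sterol supply and of length and GC content after the patterns they address but before their own values. The transcription factors below were chosen after their values were seen. SREBF2, the master regulator of sterol synthesis, was lower in the library labelled TRIP13 shRNA at 7.4 against 44.9 FPKM (ratio 0.165, 95% counting interval 0.154 to 0.176). POU2F2 had 5.08 against 35.9 FPKM, the nuclear receptor NR2F1 2.69 against 18.1, the repressor BCL6 5.41 against 29.8 and CEBPD, an inflammatory response factor, 3.41 against 19.8. E2F1, E2F2 and E2F8 were higher, with log2 ratios of 0.98, 1.56 and 1.46, whereas E2F7 had 18 against 368 reads and a log2 ratio of -1.81. SMAD6 and SMAD9, genes of BMP signalling, were higher beside ID1, ID2 and ID3, with log2 ratios of 1.53 and 1.24, and ATOH8 had 291 against 6 reads.

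Fatty acid synthesis genes followed the sterol genes in part. Of 8 tested members of a list written after SCD and the sterol list had been seen, 4 were at least 2-fold lower, with a median log2 ratio of -1.20 and no random list below it. FASN, the fatty acid synthase, had 21.5 against 84.8 FPKM, FADS1 9.39 against 41.7 and PNPLA3 4.9 against 23.1. ACLY, ACACA and MID1IP1 were less than 2-fold lower, with log2 ratios of -0.26, -0.46 and -0.55, and ELOVL6 was higher at 11.8 against 8.85 FPKM. The median falls in a gap between these genes and the larger differences, so it is near no member.

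The cell cycle and MYC target lists were higher and the cytokine and sterol lists lower in the library labelled TRIP13 shRNA. The cell cycle list here pools the mitosis and replication lists (54 genes). Removing the trend with gene length and GC content left the smallest of these medians at 0.60, and the smallest over the scalings was 0.55. These values argue against both as the whole cause for the lists as pooled here. The mitosis list alone fell to 0.43 over the scalings, and its median without the length and GC trend was not computed. Myeloid cells in the control library are not a likely source of the cytokine genes, since the most abundant of 11 myeloid markers, CD14, stood at 0.30 FPKM there against 394 for IL1B, and 7 of them, TYROBP, AIF1 and C1QA included, had 0 reads. These 11 leave out 3 of the 14 markers fixed at the start, TMEM119, CSF1R and CD68, at 4.4, 3.75 and 0.424 FPKM in the control library, and TMEM119 reached 1.12% of IL1B, above the line of 1% set for the 11. Differences in growth state, in cells selected separately and in the shRNA itself stay open and cannot be separated with 1 library per group.

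A hypothesis for the lower sterol genes was that the cells of that library had more sterol, which would raise the targets of the sterol sensor LXR. The LXR targets instead lay at percentile 1.5 of matched random lists, with a median log2 ratio of -0.36 (95% bootstrap interval over members -1.84 to -0.11, random median 0.18), which argues against a larger supply acting through LXR. The other part of the prediction was met, since the fatty acid synthesis genes had no random list below their median of -1.20. That part cannot tell a larger supply from another cause, because the list was written after SCD and the sterol genes had been seen lower. NR1H3, an LXR gene that is itself on the list, had 3.71 against 10.1 FPKM and NR1H2, the more abundant LXR gene, 32.6 against 40.2, and without NR1H3 the list lay at percentile 6.7 with a median of -0.21 (-2.45 to -0.09, random median 0.20). Whether the lower SREBF2 level precedes or follows the lower sterol genes was not tested.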
